A study of Mus musculus with 22 samples.

How the data were processed

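Expression was measured on 22 Affymetrix MoGene 1.0 ST arrays, which carry probes along whole transcripts, from sorted mouse microglia in 8 groups of 2 or 3 arrays. The values deposited by the authors are probe set intensity on a linear scale, normalized between arrays by RMA, the standard background correction, quantile normalization and summarisation for these arrays. The RMA version and settings are not given in the sources used here. The deposited table holds 28098 probe sets with values from 1.62 to 11568 and 2 missing cells. Because the intensity values were linear, log2 was taken before any test. RMA gives all arrays nearly the same distribution, so a change in the total amount of RNA per cell cannot be seen.

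Probe sets were named through the platform's probe table, in which 22961 of the probe sets are listed, 21640 with a single gene and 1321 with several. The 5137 unlisted probe sets and those with several genes were left out. Of the single-gene probe sets 21553 had a gene identifier in the RefSeq annotation of assembly GRCm38.p6, and no symbol had to be updated. That annotation served only for names and for which genes share a chromosome. The labels do not name a genome build for the array, so no coordinates are given. Each gene was represented by the probe set with the highest mean, and kept where it lay above the array's 50th percentile on at least 2 arrays, which left 11830 of 19937 genes.

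Groups were taken from the labels. WT control and KO control held 2 arrays each and the other groups 3. The 6 KO arrays with contradictory labels stand as set A and set B. The labels also mention 2 weeks of feeding before the treatment and a longer arm, while the array labels say 4 weeks. The replicate numbers were tested for pairing and used only as an alternative.

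Differences were tested with limma 3.58.1 in R 4.3.3. One model held the 8 group means of all 22 arrays, with 14 residual degrees of freedom and a prior of 5.49, and 18 contrasts were taken from it, 2 of them differences of differences. Benjamini-Hochberg adjustment ran over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Errors are standard errors from this model unless SD is named, and all tests are two-sided unless stated. Because the spread is shared between groups, a comparison can depend on arrays outside it.

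In total 31 gene lists were fixed, of which 29 had at least 3 measured members. They cover microglial states, pathways and markers of other cells, and the report names each that was called. Neuron and erythroid lists had too few measured members and were not tested. Each list was tested with camera of limma at a preset correlation of 0.01, adjusted over lists. Its members were counted over all genes tested and adjusted over the list alone. An estimated correlation and fry were alternatives, the second of which tests whether a list's genes move on balance one way without comparing them with other genes.

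Genes are named by a rule. For each comparison it takes up to 8 called genes with the largest rise and up to 8 with the largest fall whose groups do not overlap (for differences of differences, all called genes), leaving out clones and unnamed loci, then up to 4 called members of each list. It always takes Trem2, Apoe, Cst7, Clec7a, Lpl, Itgax, Spp1, Axl, P2ry12, Tmem119, Cx3cr1, Csf1r, Hmox1, Nqo1, Mki67 and Mbp, and only these for sets A and B against WT. Spp1 had no single-gene probe set and was not analysed here. Nqo1 (log2 2.67 to 3.57) and Mki67 (4.24 to 5.18) lay near or below the array medians of 5.17 to 5.27 and were removed by the filter. The lists, this rule, the comparisons and all alternatives were fixed before the data were examined, except for 2 alternatives that leave out 3 arrays low in immediate-early genes or add the immediate-early mean as a covariate.

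The alternatives were the replicate number as a block, only the arrays of the groups compared, no filter and a filter at the 75th percentile, quantile normalization, centring each array on its median, the mean of all probe sets of a gene, limma's trend and robust options, array weights, a change of at least 2-fold, an adjusted p under 0.01, and leaving out each array in turn.

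The workflow was run on data simulated with the same groups and spread. For WT cuprizone against control it recovered 48%, 92% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 4 false calls. For the genotype difference of cuprizone effects it recovered 8%, 64% and 98%, with 11 false calls. All 29 lists raised by 0.5 (log2) were recovered, and 1 of 790 unchanged lists was called. Correlated genes were not simulated, so the list rate does not cover them.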

Results

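Gene expression was measured on 22 mouse gene arrays in microglia, the resident macrophages of the brain, which had been sorted as cells positive for CD11b, CD45 and F4/80. The mice were wild type (WT) or lacked Trem2 (knockout, KO), a lipid-sensing receptor of myeloid cells that signals through the adaptor Tyrobp. They had been fed normal chow (control), cuprizone, Covi-Ox, or both additives. Cuprizone is a copper chelator that kills oligodendrocytes and strips myelin, and Covi-Ox is a mixture of tocopherols, members of the vitamin E family. By the labels the treated diets held cuprizone at 0.2% of the feed or Covi-Ox at 0.1% and were given for 4 weeks. WT control and KO control had 2 arrays each. WT cuprizone, WT Covi-Ox, WT both and KO cuprizone had 3 arrays each.

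The remaining 6 KO arrays carry labels that contradict each other. For 3 of them, called set A here, the title gives both additives and the other fields give Covi-Ox alone. For the other 3, called set B, the title gives Covi-Ox alone and the other fields give both. Values for these arrays are reported under the name of the set, and neither reading was chosen. The labels do not say that replicates are separate animals, so p-values measure only the spread between samples.

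Array medians ran from 36.1 to 38.6 intensity units. Levels near or below them are not exact, so neither is a fold or its rank where a group lies there. Among others this holds in WT control, WT Covi-Ox and all KO groups for Gpnmb (23.8 to 52.0), Mmp12 (21.3 to 35.5), Olr1 (14.8 to 26.3), Itgax (20.4 to 59.3), Ch25h, Fn1, Bhlhe40, Fam20c, Atp6v0d2, Il12b and Flt1, in all KO groups for Lpl (25.4 to 63.1), Lrmda and Mid1, in WT cuprizone for Olr1 (74.6, 39.8 and 43.1), Atp6v0d2, Il12b, F3, Cd69, Ckap2l, Lsmem1 and Rasgrf2, and in the controls and WT Covi-Ox for Apoc1 and Ifit2. A difference between 3 and 2 arrays had a median SE of 0.151 on the log2 scale over the 11830 genes tested, and one between 3 and 3 arrays a median SE of 0.136. Immediate-early genes such as Fos and Jun, which respond within minutes to cell dissociation, were low on 3 arrays, named the 3 low arrays here. The mean of the 24 measured members of that list was 8.77 on WT cuprizone 3, 9.09 on KO cuprizone 2 and 9.10 on KO cuprizone 3. It lay between 10.02 and 10.30 on the other 19 arrays. KO control 2 stood apart on the third axis of a principal component analysis (9.3% of the variance), at 31.5 against -13.8 to 5.5, and the log2 difference between the KO control arrays had an SD of 0.388 over genes, against 0.24 for WT control.

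Trem2 itself separated the genotypes on every diet. Its probe set (10445781) had a geometric mean intensity of 1320 in WT control and 88.6 in KO control, a difference of -3.89 ± 0.14 (log2, SE, n = 2 and 2), or 14.8-fold lower in KO (adjusted p = 2.17e-13). On cuprizone the difference was -3.96 ± 0.11 (n = 3 and 3, adjusted p = 6.56e-15). Set A lay 15.7-fold and set B 14.3-fold below WT both. All 11 KO arrays lay below all 11 WT arrays. A probe set can cover exons outside the deleted part of a gene, so the remaining KO signal is not read as transcript. Cuprizone left Trem2 within the replicate spread in WT (0.15 ± 0.13, adjusted p = 0.607).

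**Figure D1:**
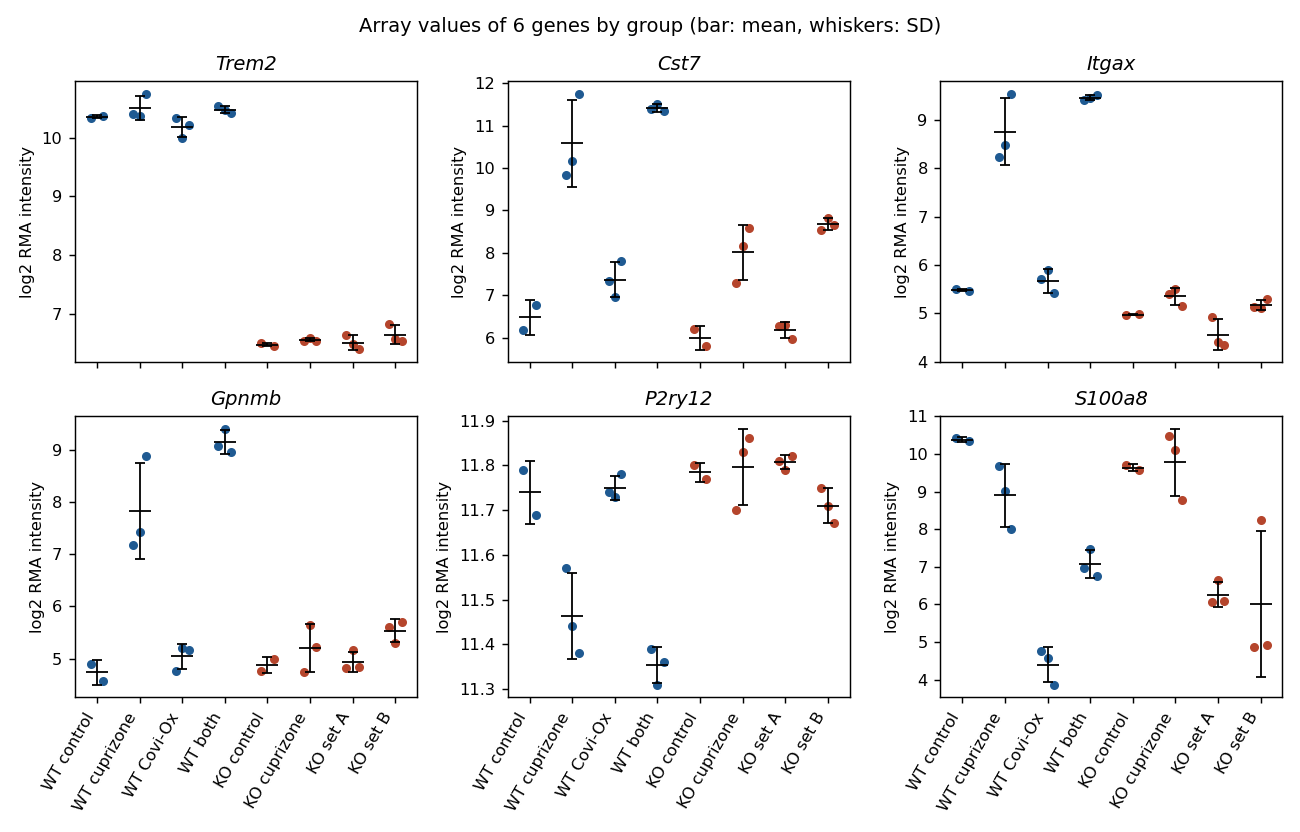
Log2 RMA intensity of Trem2, Cst7, Itgax, Gpnmb, P2ry12 and S100a8 on each array (points, blue for WT and red for KO), by diet group, with the group mean (bar) and SD (whiskers); the vertical scales differ between panels and do not start at 0. Trem2 is near 10.4 in WT control and near 6.5 in KO control, Cst7 reaches 10.59 in WT cuprizone and 8.01 in KO cuprizone, and S100a8 is at 10.39 in WT control and 4.40 in WT Covi-Ox.

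Cuprizone raised late disease-associated microglia (DAM) genes and genes of lipid handling in WT microglia. The largest rises were those of Cst7 (probe set 10476945) by 4.10 ± 0.40 (log2, SE, n = 3 and 2, 17.2-fold), and Lpl, lipoprotein lipase, by 3.36 ± 0.30 (10.3-fold). Itgax, which encodes CD11c, rose by 3.26 ± 0.25 (9.61-fold), Apoc1, an apolipoprotein, by 3.14 ± 0.57 (8.83-fold) and Gpnmb by 3.09 ± 0.34 (8.53-fold). Ch25h rose by 2.95 ± 0.55, Fn1 by 2.90 ± 0.54, and Mmp12 by 2.89 ± 0.15. Their adjusted p-values ran from 1.55e-10 for Mmp12 to 0.00512 for Ch25h, and every cuprizone array lay above both control arrays for these 8 genes. Axl rose by 2.89 ± 0.24 and Clec7a by 2.83 ± 0.21. Dnajb1 fell by 1.25 ± 0.32 (log2), the largest fall, and Bank1 by 1.13 ± 0.21. Nabp1, Slc39a12, Pcf11, Zranb1, Ice1 and Ccnl1 fell by between 1.03 and 0.85.

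In all, 296 of 11830 genes passed adjusted p under 0.05 with limma, 213 higher and 83 lower in cuprizone. Without WT control 1 the count was 69, without WT control 2 it was 87, and without WT cuprizone 3, a low array, it was 126. Of the 55 called genes named by the fixed rule, 17 kept their call whichever single array was left out. These were Cst7, Lpl, Itgax, Gpnmb, Mmp12, Axl, Clec7a, Fabp5, Olr1, Gla, Nceh1, Ccl5, Cxcl16, Il1rn, Ifi27l2a, Ifit2 and Oasl2, and the others lost it at least once. With the spread estimated only from these 5 arrays 9 genes passed, Cst7 not among them.

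By gene list, the late DAM genes moved furthest in WT cuprizone. Of 19 measured members 16 rose and 19 rose when adjusted over the list alone (mean 1.90, adjusted p = 1.42e-43, and adjusted p = 0.00357 with a correlation estimated from the data, given after each such p as estimated). Of the 14 genes of lipid uptake and storage 4 rose over all genes and 6 when adjusted over the list alone (mean 0.76, adjusted p = 3.72e-07, estimated 0.00866). They were Lpl, the fatty acid binding protein Fabp5 (2.43 ± 0.33), the oxidised LDL receptor Olr1 (1.67 ± 0.20) and the lipid droplet protein Plin2 (0.77 ± 0.18). Of the 16 genes of cholesterol efflux and LXR targets 5 rose over all genes and 10 adjusted over the list alone (mean 0.83, adjusted p = 2.35e-09, estimated 0.0189). Nceh1 rose by 1.97 ± 0.26. Apoe did not pass (0.55 ± 0.15, adjusted p = 0.0518). Cholesterol synthesis was not called (19 measured, mean 0.10, adjusted p = 0.162).

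The interferon response followed, with 12 of 24 measured members higher and 14 adjusted over the list alone (mean 0.85, adjusted p = 1.35e-18, estimated 0.0189). Ifi27l2a rose by 2.05 ± 0.34, Ifit2 by 1.92 ± 0.30 and Oasl2 by 1.80 ± 0.27. Glycolysis and hypoxia genes rose for 8 of 16 members and 13 adjusted over the list alone (mean 0.64, adjusted p = 1.42e-13, estimated 0.0189), with Pgk1 at 1.05 ± 0.20, Pkm at 1.01 ± 0.18 and Tpi1 at 0.92 ± 0.15. MHC class I had 1 of 10 members higher, Psme1, and 6 adjusted over the list alone (mean 0.36, adjusted p = 1.36e-05, estimated 0.0189).

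Further lists were called with the preset correlation only, though without the 3 low arrays the lysosomal (estimated 0.033), homeostatic and cell cycle (estimated 0.0432 each) calls held with an estimated one. Early DAM genes had 2 of 9 members higher and 3 adjusted over the list alone (adjusted p = 0.000392, estimated 0.111). Lysosomal genes had 8 of 36 higher and 14 adjusted over the list alone, with Gla at 1.51 ± 0.19 and Atp6v0d2 at 1.33 ± 0.27 (adjusted p = 1.57e-10, estimated 0.0766). Homeostatic microglia genes had 1 of 20 lower, Upk1b, and 7 adjusted over the list alone (mean -0.25, adjusted p = 9.62e-08, estimated 0.202). P2ry12, Tmem119, Cx3cr1 and Csf1r, markers of resting microglia, stood at -0.28, -0.33, -0.19 and -0.14 and did not pass. Cell cycle genes had 1 of 18 higher, Birc5, and 4 adjusted over the list alone (adjusted p = 6.99e-06, estimated 0.0932). Oxidative phosphorylation had 1 of 28 higher, Cox4i1, and 6 adjusted over the list alone (adjusted p = 6.24e-07, estimated 0.205). The ATF4 and amino acid list had 1 of 19 higher, Psat1 (1.39 ± 0.32), with 2 higher and 2 lower adjusted over the list alone (adjusted p = 0.0109, estimated 0.204).

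Other lists moved in the same arrays. The immediate-early list was lower by a mean of -0.48 (0 of 24 members called, adjusted p = 0.000111, estimated 0.426), and the neutrophil list by a mean of -0.74 (0 of 9 called, adjusted p = 0.00802, estimated 0.205). Border macrophage genes had 1 of 12 lower, Pf4, by 0.76 ± 0.20 on the log2 scale (adjusted p = 0.00631, estimated 0.391). NRF2 antioxidant genes, inflammatory cytokines, with Ccl5 at 2.29 ± 0.35 and Il1rn at 1.10 ± 0.17, and TREM2 and DAP12 signalling genes were not called (adjusted p = 0.0596, 0.335 and 0.138). Hmox1 (0.03 ± 0.27) and Mbp (0.07 ± 0.14) did not pass. Without the 3 low arrays 184 genes passed, and with the immediate-early mean as a covariate 188 did. In the first of these fits the immediate-early mean was -0.01 (adjusted p = 0.792), the neutrophil and ATF4 lists were not called (adjusted p = 0.0641 and 0.155), and inflammatory cytokines, at a mean of -0.05 with all arrays, were called higher (mean 0.32, adjusted p = 6.32e-06, estimated 0.156). With the covariate that list was called too (mean 0.40, adjusted p = 2.88e-08). Both fits were chosen after the data had been seen.

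**Figure D2:**
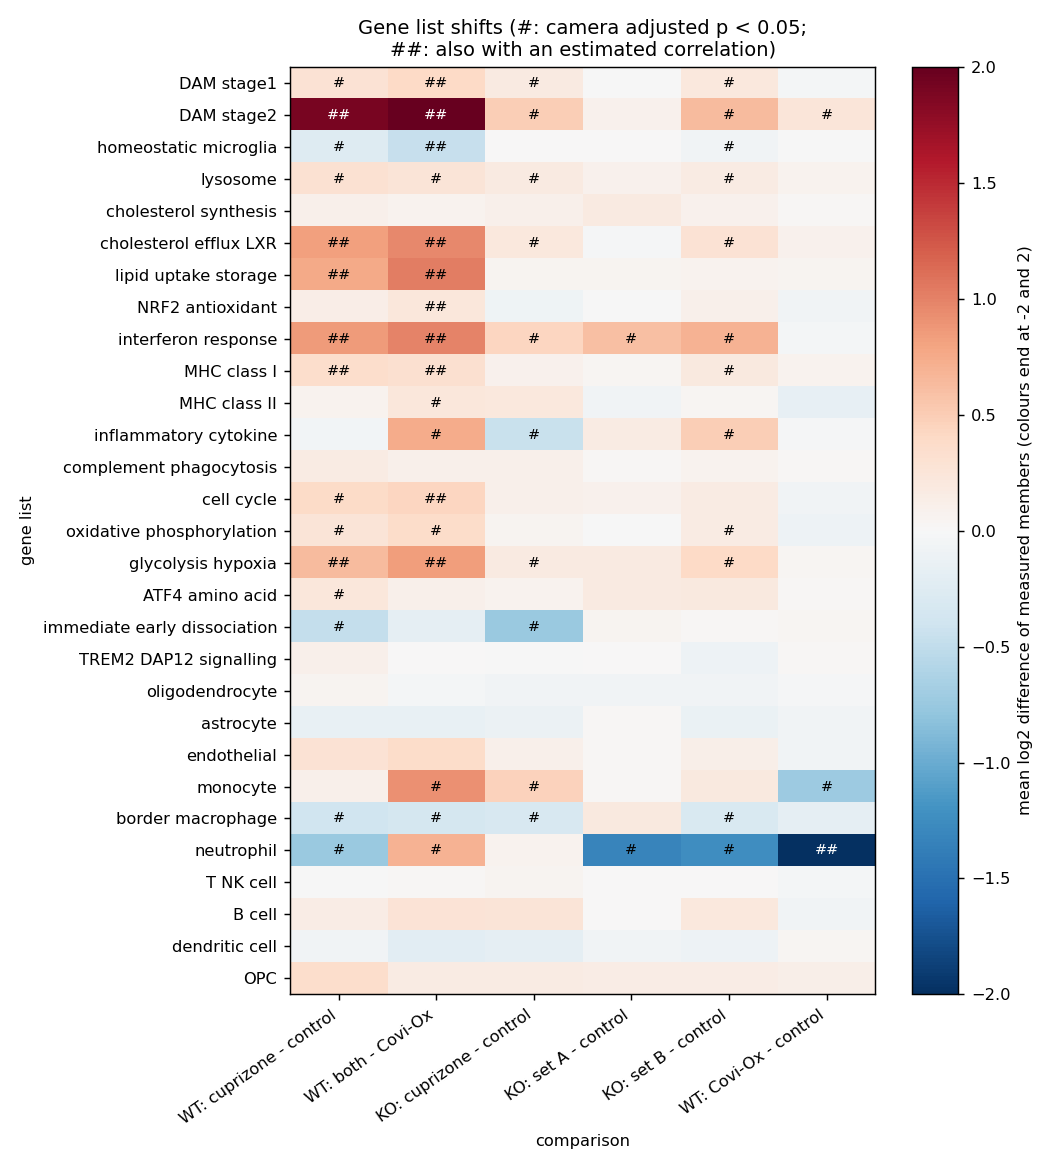
Mean log2 difference of the measured members of each of 29 gene lists (vertical axis) in 6 comparisons (horizontal axis), as colour from -2 (blue) to 2 (red), the ends of the colour scale; # marks lists called by camera and ## those called also with an estimated correlation. The late DAM list (DAM stage2) is at 1.90 and 2.11 in the WT cuprizone comparisons and at 0.49 in KO cuprizone, and the neutrophil list is at -2.34 in WT Covi-Ox.

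In KO microglia 5 genes passed between cuprizone and control, and none belongs to a fixed list. Stxbp4 fell by 2.51 ± 0.45 (log2, SE, n = 3 and 2), Cdc5l by 1.22 ± 0.20, Chordc1 by 1.08 ± 0.19 and Kat8 by 1.03 ± 0.18. Zfp512b rose by 0.59 ± 0.10. Cst7 stood at 2.01 ± 0.40 (adjusted p = 0.0747), Clec7a at 0.97 ± 0.21 (adjusted p = 0.086), Lpl at 0.80 ± 0.30, Axl at 0.70 ± 0.24 and Itgax at 0.38 ± 0.25, none of which passed. P2ry12, Tmem119, Cx3cr1, Csf1r, Apoe, Hmox1 and Mbp (-0.49 to 0.14) did not pass. At an unadjusted p under 0.05 there were 1591 genes. The count of 5 (1 higher, 4 lower, 20% higher) was 12 after quantile normalization, with 58.3% higher. It was 765 without KO control 1, 205 without KO cuprizone 1, 1 without KO cuprizone 3 and 0 without KO control 2. All 5 calls were lost in at least 1 of these fits. The numbers without the 3 low arrays and with the immediate-early covariate were 9 and 2.

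Of the lists, 10 were called in KO cuprizone and none of these calls held with an estimated correlation, where the adjusted p-values were 0.418 or higher. No member of these lists was called over all genes. The late DAM genes had a mean of 0.49 with 11 of 19 higher adjusted over the list alone (adjusted p = 1.87e-08, estimated 0.418). Interferon genes had a mean of 0.43 with 8 of 24 higher adjusted over the list alone (adjusted p = 7.12e-07) and lysosomal genes a mean of 0.18 with 5 of 36 (adjusted p = 1.42e-06), each with estimated adjusted p = 0.418. Early DAM genes (mean 0.18, adjusted p = 0.0129) and monocyte genes (mean 0.47, adjusted p = 0.0248) also had estimated adjusted p = 0.418. Cholesterol efflux (0.22, adjusted p = 0.0284) and glycolysis (0.17, adjusted p = 0.021) had estimated adjusted p = 0.493 and 0.517. The immediate-early list was lower in the same arrays by a mean of -0.75, with 6 of 24 lower adjusted over the list alone (adjusted p = 3.57e-11, estimated 0.418). Inflammatory cytokines (mean -0.45, adjusted p = 0.0284) and border macrophage genes (mean -0.32, adjusted p = 0.0248) moved the same way, with estimated adjusted p = 0.609 and 0.582. Without the 3 low arrays KO cuprizone 1 was alone in its group, so only sizes are given. Both of these lists were then higher instead, the immediate-early mean was -0.08 and the late DAM mean 0.42.

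The difference between the cuprizone effects of the genotypes was tested directly. Of the genes called, 8 are late DAM and 2 lipid uptake genes, Lpl being both, and others are in no list, Mmp12, Bhlhe40, Capg and Fam20c among them. The effect was smaller in KO by -2.88 ± 0.36 (log2, SE, n = 3, 2, 3 and 2) for Itgax, -2.82 ± 0.21 for Mmp12, -2.77 ± 0.48 for Gpnmb and -2.56 ± 0.43 for Lpl. Bhlhe40 stood at -2.77 ± 0.55, Axl at -2.19 ± 0.34, Capg at -2.15 ± 0.41 and Fam20c at -2.10 ± 0.18. Clec7a was at -1.85 ± 0.29, Olr1 at -1.61 ± 0.28, Gla at -1.39 ± 0.26 and Cxcl16 at -0.80 ± 0.16. The effect was more positive in KO for Eif2s3y (1.81 ± 0.36), Clec12a (1.29 ± 0.27), Zranb1 (1.17 ± 0.24), Csmd3 (0.92 ± 0.19) and Maml2 (0.83 ± 0.16). The Y-linked Eif2s3y was at 5.91 and 6.18 in KO control, 6.61 on KO cuprizone 2 and 7.06 or higher elsewhere. Its differences with KO control rest mainly on these low arrays, whose sex was not tested. Cst7, at -2.09 ± 0.57, did not pass (adjusted p = 0.184), nor did Apoe, P2ry12, Tmem119, Cx3cr1, Csf1r, Hmox1, Mbp or Trem2 (-0.52 to 0.29).

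In this test 27 genes passed, 5 with a more positive and 22 with a more negative effect in KO (18.5% positive), and 1192 were at an unadjusted p under 0.05. After centring each array on its median 4.35% of 23 calls were positive. The count was 265 without KO control 1 and 6, 8, 7, 14 and 15 without WT control 1, WT control 2, KO control 2, KO cuprizone 2 and KO cuprizone 3. Itgax, Mmp12 and Fam20c, of the 17 named genes, kept their call whichever array was left out. From these 10 arrays alone 4 genes passed, Itgax not among them, and 88 passed with the immediate-early covariate. Across the 11830 genes the cuprizone effects of the genotypes had Pearson r = 0.311 and Spearman rho = 0.24, described only, since genes are not independent replicates. The Pearson value was 0.208 without KO control 1, and it was 0.124 without the 3 low arrays. Among the 213 genes that cuprizone raised in WT the median effect was 0.92 in WT and 0.24 in KO, and 212 had the smaller value in KO. That list was chosen on its WT effect, which raises the WT value by selection. Among the 154 genes raised at least 2-fold in WT both minus WT Covi-Ox, chosen on none of these arrays, the medians were 1.13 in WT and 0.24 in KO.

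**Figure D3:**
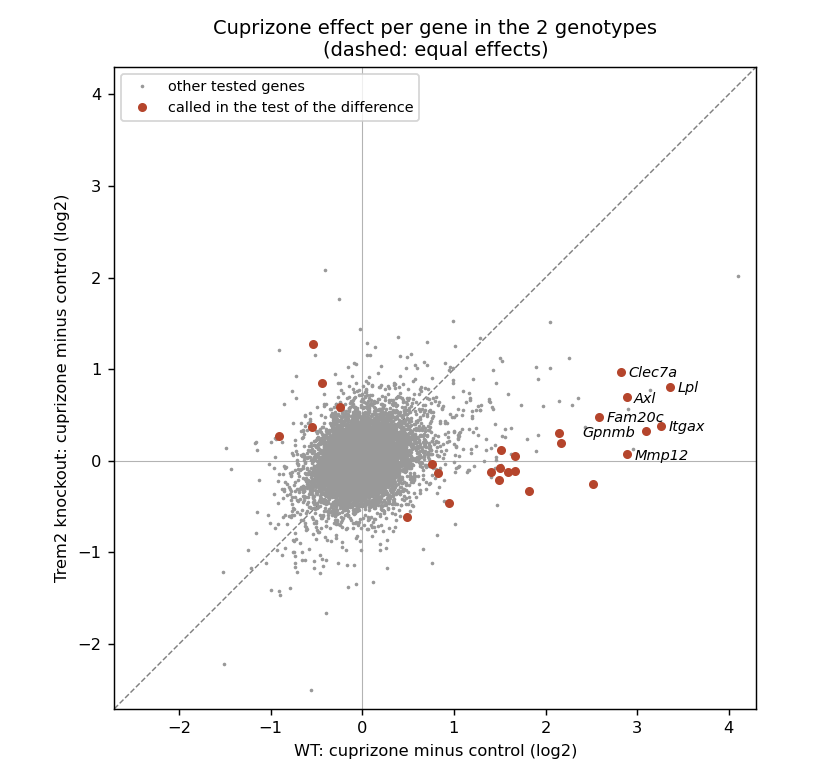
Cuprizone minus control (log2) of each tested gene in WT (horizontal axis) and in KO (vertical axis); red points are the 27 genes called in the test of the difference, grey points the other genes, and the dashed line marks equal effects. Itgax, Gpnmb, Lpl, Axl, Clec7a, Fam20c and Mmp12 lie between 2.5 and 3.4 in WT and below 1 in KO.

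Among the lists in this test, late DAM genes were lower in KO by a mean of -1.41, with 8 of 19 called and 15 adjusted over the list alone (adjusted p = 4.73e-24, estimated 0.0241). Lipid uptake genes were lower by a mean of -0.70, with 2 of 14 called and 5 adjusted over the list alone (adjusted p = 2.89e-06, estimated 0.0218). Glycolysis (mean -0.47, 6 of 16 lower adjusted over the list alone, adjusted p = 6.15e-06), cholesterol efflux (mean -0.61, 3 of 16, adjusted p = 0.000372), NRF2 genes (mean -0.22, adjusted p = 0.00509) and MHC class I (mean -0.27, adjusted p = 0.00514) had estimated adjusted p = 0.189. Interferon genes (mean -0.43, adjusted p = 4.81e-05), homeostatic genes (mean 0.25, adjusted p = 6.84e-06), cell cycle genes (mean -0.28, adjusted p = 0.00514) and neutrophil genes (mean 0.81, adjusted p = 0.00597) had estimated adjusted p = 0.322. Oxidative phosphorylation (mean -0.21, adjusted p = 0.000725) and inflammatory cytokines (mean -0.40, adjusted p = 0.00328) had estimated adjusted p = 0.52 and 0.546. Without the 3 low arrays KO cuprizone 1 was alone in its group. The late DAM mean was then -1.21 and the lipid uptake mean -0.36, and inflammatory cytokines and cell cycle genes pointed the other way.

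On normal chow the genotypes differed in 8 genes, 6 lower and 2 higher in KO. Besides Trem2, Mid1 was lower by -2.60 ± 0.26 (log2, SE, n = 2 and 2), the Y-linked Eif2s3y by -1.96 ± 0.28, Lrmda by -1.89 ± 0.32 and Maml2 by -0.69 ± 0.13. Rasgrf2 was higher by 2.84 ± 0.25 and Nnt by 0.91 ± 0.16. The clone G530011O06Rik at -6.20, is named here after its value was seen. Lpl (-1.05 ± 0.33, adjusted p = 0.298), Cst7 (-0.49 ± 0.44), Itgax (-0.52 ± 0.28), Clec7a (-0.49 ± 0.23) and Axl (-0.23 ± 0.26) did not pass. Apoe, Tmem119, P2ry12, Cx3cr1, Csf1r, Hmox1 and Mbp (-0.25 to 0.16) did not pass either. Late DAM genes (mean -0.29, 2 of 19 lower adjusted over the list alone) and glycolysis genes (mean -0.26, 1 of 16) were called (adjusted p = 0.0204 each, estimated 0.821). There were 1244 genes at an unadjusted p under 0.05. Without KO control 1 the count was 701 and without KO control 2 it was 5. Trem2, Mid1, Eif2s3y and Rasgrf2 kept their call without any 1 array, and Lrmda, Maml2 and Nnt did not.

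On cuprizone 146 of the 213 genes that cuprizone raised in WT were called lower in KO and 67 were not called, a list chosen on the same WT cuprizone arrays. Of the 154 genes chosen on a contrast of other arrays 100 were called lower and 54 not. Lpl was lower by -3.60 ± 0.27 (log2, SE, n = 3 and 3, 12.2-fold), Itgax by -3.40 ± 0.23 (10.6-fold), Mmp12 by -3.16 ± 0.13 (8.95-fold), Ch25h by -2.93 ± 0.49 (7.62-fold) and Gpnmb by -2.62 ± 0.30 (6.15-fold). Cst7 (-2.57 ± 0.36), Axl (-2.42 ± 0.22), Clec7a (-2.35 ± 0.18), Fabp5 (-2.27 ± 0.30) and Apoe (-0.66 ± 0.13) were lower as well. Of 20 homeostatic microglia genes 6 were higher in KO, Gpr34 (0.54 ± 0.09), P2ry13 (0.46 ± 0.11), P2ry12 (0.33 ± 0.08) and Tmem119 (0.33 ± 0.09) among them, while Cx3cr1 (0.28) and Csf1r (0.11) did not pass. The list's call was lost with an estimated correlation (adjusted p = 0.117). A fit without the 3 low arrays leaves KO cuprizone 1 alone in its group, so it does not decide this call. Rasgrf2 (2.72 ± 0.20), Csmd3 (1.24 ± 0.12), Glo1 (1.14 ± 0.15), and Ypel1, Slc39a12, Nnt, Apobec2 and Gpr165 (0.84 to 1.10) were the largest positive differences by the fixed rule. Mid1 was lower by -2.80 ± 0.21 and Fn1 by -2.72 ± 0.48. Hmox1 (-0.76) and Mbp (-0.38) did not pass.

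Here 450 genes passed, 97 higher and 353 lower in KO (21.6% higher). The share was 36.5% of 408 after quantile normalization and 7.17% of 711 after centring each array on its median, so it depends on the scaling. The count was 273 without WT cuprizone 3, 249 without KO cuprizone 2 and 207 without KO cuprizone 3. Without all 3, the low arrays, the count was lower too, but KO cuprizone 1 is then the only KO array left. With the immediate-early covariate 807 passed. From these 6 arrays alone the count was 39. Of the 66 called genes named, 36 kept their call without any 1 array, including the 10 lower genes named first, Fn1, Mid1, Gpr34, Rasgrf2, Csmd3, Glo1 and Nnt. P2ry12, P2ry13, Tmem119, Ypel1, Slc39a12, Apobec2 and Gpr165 lost it at least once.

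Among the lists, late DAM genes were lower in KO cuprizone than in WT cuprizone for 15 of 19 members and for 17 adjusted over the list alone (mean -1.70, adjusted p = 7.57e-33, estimated 0.0107). Glycolysis genes were lower for 10 of 16 and 14 adjusted over the list alone (mean -0.72, adjusted p = 2.8e-14, estimated 0.0217). Lipid uptake genes were lower for 4 of 14 and 6 adjusted over the list alone (mean -0.79, adjusted p = 7.58e-07, estimated 0.0107). NRF2 genes were lower for 3 of 21 and 4 adjusted over the list alone (mean -0.32, adjusted p = 5.69e-05, estimated 0.0217). The immediate-early list had a mean of -0.26 in the same arrays and was not called (adjusted p = 0.218), though Egr2, one of its members, was lower by -1.37 ± 0.33.

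The other calls in this comparison were lost with an estimated correlation. Interferon genes were lower for 7 of 24 and 17 adjusted over the list alone (adjusted p = 1.36e-11, estimated 0.086). Homeostatic genes were higher for 11 of 20 adjusted over the list alone (adjusted p = 2.01e-11). MHC class I genes were lower for 3 of 10, with 1 higher and 6 lower adjusted over the list alone (adjusted p = 0.000409, estimated 0.0527). Cholesterol efflux genes were lower for 4 of 16 and 6 adjusted over the list alone (adjusted p = 0.000215, estimated 0.127). Inflammatory cytokines were lower for 4 of 23 and for 10 adjusted over the list alone (adjusted p = 6.19e-08, estimated 0.192). Early DAM genes were lower for 2 of 9 and 4 adjusted over the list alone (adjusted p = 0.00309), and oxidative phosphorylation for 2 of 28 and 3 adjusted over the list alone (adjusted p = 4.6e-08), both with estimated adjusted p = 0.19. Lysosomal genes were lower for 4 of 36 and 6 adjusted over the list alone (adjusted p = 0.00266, estimated 0.384). Cell cycle genes (2 of 18 lower) and ATF4 genes (1 of 19, Asns) had adjusted p = 0.00892 and 0.0247, estimated 0.294 and 0.22. Without the 3 low arrays, with KO cuprizone 1 the only KO array left, these last lists pointed the other way.

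Covi-Ox alone changed 4 genes in WT. S100a8 and S100a9, which encode the calprotectin subunits abundant in neutrophils, fell by 5.99 ± 0.70 and 5.24 ± 0.71 on the log2 scale (n = 3 and 2, adjusted p = 0.000332 and 0.0019). Tagap rose by 1.09 ± 0.13 and Leap2 by 0.88 ± 0.15. S100a8 read 14.7 to 27.2 on the Covi-Ox arrays, below the array medians, and S100a9 24.8 to 79.3, so the sizes of these falls are not exact. With limma 862 genes were at an unadjusted p under 0.05. Of 9 measured neutrophil genes 2 fell and 7 fell adjusted over the list alone (mean -2.34, adjusted p = 2.04e-14, estimated 0.0069). Monocyte genes had 0 of 9 members called and 4 lower adjusted over the list alone (mean -0.73, adjusted p = 0.000271, estimated 0.0564). The late DAM list was called with 0 of 19 members passing and 1 higher adjusted over the list alone (mean 0.24, adjusted p = 0.00358, estimated 0.882). NRF2 antioxidant genes were not called, and Hmox1 stood at -0.22 ± 0.27. Cst7 (0.88 ± 0.40), Clec7a (0.49), Axl (0.39), Lpl (0.19), Itgax (0.18), Apoe, Tmem119, Cx3cr1, P2ry12, Csf1r, Mbp and Trem2 (-0.18 to 0.06) did not pass. Without WT control 1 or WT control 2 the count was 2 each, with Leap2 and S100a9 lost. The count was 18 from these 5 arrays alone, 52 with array weights and 36 without the 3 low arrays, where late DAM and monocyte genes had estimated adjusted p = 0.0194 and 0.0123.

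Adding Covi-Ox to cuprizone changed 18 genes in WT, 13 higher and 5 lower, with 957 at an unadjusted p under 0.05. Olr1 rose by 2.48 ± 0.18 (log2, SE, n = 3 and 3, 5.57-fold, adjusted p = 1.9e-07), Atp6v0d2 by 1.49 ± 0.24, F3, tissue factor, by 1.45 ± 0.19 and Cd69 by 1.19 ± 0.23. Ckap2l rose by 1.10 ± 0.22, Il12b by 1.01 ± 0.12, Cd44 by 0.99 ± 0.14 and Lsmem1 by 0.90 ± 0.17. Il7r, Crybb1, Sult1a1, Abcb4 and Zfp212 fell by between 0.69 and 0.48 on the log2 scale. Some genes raised by cuprizone stood higher without passing, with Cst7 at 0.83 ± 0.36, Itgax at 0.71 ± 0.23, Clec7a at 0.60 ± 0.18, Lpl at 0.59 ± 0.27 and Axl at 0.50 ± 0.22. This rests on WT cuprizone 1 and 2, since WT cuprizone 3 lay above every WT both array for Cst7 (11.75 against 11.34 to 11.51, log2), Lpl (10.03 against 9.63 to 9.93), Itgax and Axl, and within their range for Clec7a. Tmem119, Csf1r, Cx3cr1, P2ry12, Apoe, Hmox1, Mbp and Trem2 (-0.36 to 0.13) did not pass. The count was 104 without WT cuprizone 3. It was 8 and 4 without WT cuprizone 1 and 2, and 6, 10 and 9 without WT both 1, 2 and 3. Olr1, F3, Il12b and Cd44 kept their call without any 1 array. From these 6 arrays alone 2 genes passed, and with array weights 150. The number without the 3 low arrays was also 150, and with the immediate-early covariate 73.

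Of the lists in this comparison, 7 were called and none held with an estimated correlation. Inflammatory cytokines had 1 of 23 members higher and 9 adjusted over the list alone (mean 0.77, adjusted p = 1.84e-18), and lipid uptake had 1 of 14, Olr1 (mean 0.33, adjusted p = 0.000846), both with estimated adjusted p = 0.115. The late DAM list had 5 of 19 higher adjusted over the list alone (mean 0.46, adjusted p = 2.13e-11, estimated 0.191). Homeostatic genes had 1 of 20 lower, Crybb1, and 5 adjusted over the list alone (mean -0.22, adjusted p = 5.26e-09), glycolysis genes a mean of 0.24 (adjusted p = 5.79e-05) and neutrophil genes a mean of -0.90 with 3 of 9 lower adjusted over the list alone (adjusted p = 0.00251), each with estimated adjusted p = 0.305. The immediate-early list was higher in the same arrays by 0.34 (adjusted p = 3.97e-05, estimated 0.703), and pointed the other way without the 3 low arrays (adjusted p = 0.0121). That fit drops WT cuprizone 3, whose late DAM mean (10.052) exceeds those of all WT both arrays (9.919 to 10.003) and so goes against the late DAM difference. In it the inflammatory mean was 0.40 (adjusted p = 2.32e-11, estimated 0.0453), the late DAM mean 0.73 (adjusted p = 9.55e-29, estimated 3.1e-05) and the neutrophil mean -1.23 (adjusted p = 3.15e-06, estimated 0.0338), and homeostatic, lipid uptake and glycolysis genes had estimated 0.00304, 0.00249 and 0.00467.

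On a Covi-Ox diet cuprizone changed 925 WT genes, 550 higher and 375 lower (490 and 496 after quantile normalization, so the majority depends on the scaling), while the direct test of the difference from its effect on normal chow called 3. Apoc1 rose by 4.79 ± 0.51 (log2, SE, n = 3 and 3, 27.6-fold), Fn1 by 4.71 ± 0.48 (26.2-fold), Ch25h by 4.31 ± 0.49 (19.8-fold), Gpnmb by 4.10 ± 0.30 (17.2-fold) and Cst7 by 4.05 ± 0.36 (16.5-fold). Bhlhe40 (3.82 ± 0.35), Itgax (3.79 ± 0.23), Lpl (3.76 ± 0.27), Olr1 (3.64 ± 0.18), Axl (3.00 ± 0.22), Atp6v0d2 (2.94 ± 0.24) and Clec7a (2.93 ± 0.18) rose as well. Gpr165 fell by 1.73 ± 0.20 on the log2 scale, Ccn1 by 1.34 ± 0.19, Bank1 by 1.28 ± 0.19, Il7r by 1.17 ± 0.13, Tagap by 1.13 ± 0.11, and Ptger3, Cd163 and Mrc1 by between 1.10 and 1.09. P2ry12 (-0.39 ± 0.08), Tmem119 (-0.61 ± 0.09), Cx3cr1 (-0.41 ± 0.09) and Csf1r (-0.31 ± 0.08) were lower and Apoe higher (0.75 ± 0.13), all past the threshold. Hmox1 (0.20), Mbp (-0.03) and Trem2 (0.30) did not pass. The count was 564 without WT Covi-Ox 2, 531 without WT both 2 and 603 without WT both 3. Of 83 named calls 62 held without any 1 array, including all genes of this paragraph that passed except Cd163, Mrc1 and Csf1r.

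This comparison shares no array with that of WT cuprizone and WT control. Of the 213 genes raised there 175 were also raised here, where 9.9 would be shared by chance (two-sided Fisher exact p = 3.2e-205), and of the 83 lower genes 25 were shared against 2.63 (Fisher exact p = 3.07e-18). Genes are not independent, so these p-values overstate the evidence. Late DAM genes rose for 18 of 19 members (19 adjusted over the list alone, mean 2.11, adjusted p = 3.83e-43, estimated 0.00377). Homeostatic genes fell for 14 of 20 (19 adjusted over the list alone, mean -0.47, adjusted p = 7.8e-17, estimated 0.0337). Interferon genes rose for 18 of 24 (20 adjusted over the list alone, mean 0.99) and glycolysis genes for 13 of 16 (13, mean 0.84), each with estimated adjusted p = 0.0154. Lipid uptake genes rose for 5 of 14 (5 adjusted over the list alone, mean 1.03, estimated adjusted p = 0.00419). Cholesterol efflux genes rose for 8 of 16 (10 higher and 2 lower adjusted over the list alone, mean 0.97), early DAM genes for 5 of 9 (6 adjusted over the list alone, mean 0.40) and MHC class I genes for 3 of 10 (5 adjusted over the list alone, mean 0.32), each with estimated adjusted p = 0.0271. NRF2 genes had 5 of 21 higher and 1 lower (6 and 1 adjusted over the list alone, mean 0.23, estimated adjusted p = 0.0412). Cell cycle genes rose for 6 of 18 (7 adjusted over the list alone, mean 0.43, estimated adjusted p = 0.0438).

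Further calls of this comparison were lost with an estimated correlation. Inflammatory cytokines rose for 9 of 23 (11 adjusted over the list alone, adjusted p = 2.41e-10, estimated 0.0928). Oxidative phosphorylation rose for 12 of 28 (15 adjusted over the list alone, adjusted p = 4.44e-11, estimated 0.0859) and lysosomal genes for 10 of 36 (11 higher and 1 lower adjusted over the list alone, adjusted p = 6.17e-06, estimated 0.158). MHC class II had 1 of 9 higher, Cd74, and 2 adjusted over the list alone (adjusted p = 0.0178, estimated 0.126). Monocyte genes had 2 of 9 higher and 5 adjusted over the list alone (mean 0.92, adjusted p = 0.00814, estimated 0.086). Neutrophil genes had 1 of 9 higher, S100a8 (mean 0.70, adjusted p = 0.0314, estimated 0.302). Border macrophage genes had 1 of 12 higher and 3 lower (mean -0.35, adjusted p = 0.0234, estimated 0.47). The fit without the 3 low arrays, none of them compared here, added the inflammatory, oxidative phosphorylation and monocyte lists (estimated 0.018, 0.0193 and 0.0258) and lost NRF2 genes (estimated 0.0639).

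Whether Covi-Ox changed the cuprizone effect in WT was tested as a difference of differences, and 3 genes passed (1 higher, 2 lower, limma) with 785 at an unadjusted p under 0.05. The effect on Olr1 was larger on Covi-Ox by 1.97 ± 0.27 (log2, SE, n = 3, 3, 3 and 2), that on Ccn1 lower by -1.86 ± 0.29 and that on Tagap lower by -1.43 ± 0.17. For Cst7 the difference was -0.05 ± 0.54, for Itgax 0.53 ± 0.34, for Lpl 0.40 ± 0.40, for Axl 0.11 ± 0.32 and for Clec7a 0.11 ± 0.28, none past the threshold. Apoe, P2ry12, Tmem119, Cx3cr1, Csf1r, Hmox1, Mbp and Trem2 (-0.27 to 0.20) did not pass. Inflammatory cytokines had 4 of 23 higher adjusted over the list alone (mean 0.80, adjusted p = 3.89e-10, estimated 0.355). Neutrophil genes (mean 1.44, adjusted p = 5.32e-06) and monocyte genes (mean 0.81, adjusted p = 0.00395) were higher, both with estimated adjusted p = 0.21, and homeostatic genes lower (mean -0.21, adjusted p = 2.57e-05, estimated 0.604). The count was 1 without WT control 2 and 32 without WT cuprizone 3. It was 40 without the 3 low arrays, where the inflammatory mean was 0.42 (adjusted p = 1.13e-07, estimated 0.122) and late DAM genes, not called above (mean 0.21, adjusted p = 0.0771), were higher by 0.49 (adjusted p = 5.85e-10, estimated 0.00434), WT cuprizone 3 with its high late DAM mean being left out. Homeostatic, lipid uptake and monocyte genes then had estimated 0.0224 each. Tagap kept its call without any 1 array, and Olr1 and Ccn1 did not.

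Set A differed from KO control in 4 genes. Eif2s3y was higher by 1.87 ± 0.25 (log2, SE, n = 3 and 2), the interferon-induced Ifit3 by 1.57 ± 0.25, Slfn2 by 1.00 ± 0.17 and Maml2 by 0.65 ± 0.11, and 1364 genes were at an unadjusted p under 0.05. Interferon genes had 2 of 24 higher and 10 adjusted over the list alone (mean 0.61, adjusted p = 1.65e-12) and neutrophil genes 5 of 9 lower adjusted over the list alone (mean -1.32, adjusted p = 3.13e-06), both with estimated adjusted p = 0.187. Cst7 (0.18 ± 0.40), Lpl (0.59 ± 0.30), Itgax (-0.41 ± 0.25), Axl (0.20 ± 0.24), Clec7a (-0.09 ± 0.21), Apoe (-0.12), Tmem119 (-0.15), Hmox1 (0.17) and Mbp (-0.36) did not pass, and P2ry12, Cx3cr1 and Csf1r stood at 0.02, 0.03 and 0.00. The count was 925 without KO control 1, 0 without KO control 2 or set A 1, and 2 without set A 3. All 4 calls were lost in at least 1 of these fits.

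Set B differed from KO control in 88 genes, 65 higher and 23 lower (73.9% higher, and 61.2% of 85 after quantile normalization). Cst7 was higher by 2.68 ± 0.40 (log2, SE, n = 3 and 2, 6.39-fold), Cxcl9 by 1.90 ± 0.31, Ifit3 by 1.78 ± 0.25, Ifi27l2a by 1.63 ± 0.34, and Lgals3bp, Cdk5rap1, Csf1 and Hcar2 by between 1.22 and 1.56. S100a9 and S100a8 were lower by -3.67 ± 0.71 and -3.63 ± 0.70, sizes that are not exact, since set B 1 and 3 read 29.0 to 37.9 and set B 2 271 and 304. Also lower were Stxbp4 by -2.77 ± 0.45 and Syne2, Dear1, Gdpgp1, Cdc5l and Orm2. Clec7a was higher by 0.97 ± 0.21. Lpl (0.85 ± 0.30), Axl (0.70 ± 0.24), Itgax (0.21 ± 0.25), Apoe, Tmem119, P2ry12, Cx3cr1, Csf1r, Hmox1 and Mbp (-0.31 to 0.28) did not pass. The count was 876 without KO control 1, where KO control 2, which stood apart, is the only control, and 0 without KO control 2, where the adjusted p of Cst7 was 0.156. It was 25, 14 and 21 without set B 1, 2 and 3, and each of the 25 named calls was lost in at least 1 of these fits. From these 5 arrays alone 3 genes passed, and with array weights 2.

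Of the lists, 12 were called between set B and KO control and none held with an estimated correlation. Late DAM genes had 4 of 19 higher and 12 adjusted over the list alone (mean 0.64, adjusted p = 1.26e-10), interferon genes 5 of 24 and 14 (mean 0.70, adjusted p = 1.97e-12) and glycolysis genes 3 of 16 and 7 (mean 0.40, adjusted p = 1.25e-07), each with estimated adjusted p = 0.23. Inflammatory cytokines had 1 of 23 higher, Tlr2, and 5 adjusted over the list alone (mean 0.49, adjusted p = 0.00016, estimated 0.48). Lysosomal genes had 1 of 36 higher, Atp6v1a, and 5 adjusted over the list alone (adjusted p = 0.000298), and cholesterol efflux a mean of 0.29 (adjusted p = 0.0151), both with estimated adjusted p = 0.471. Early DAM, MHC class I and oxidative phosphorylation genes (higher) and homeostatic and border macrophage genes (lower) were called too, with adjusted p from 0.00431 to 0.0428. Neutrophil genes were lower in the same arrays, with 2 of 9 members called (mean -1.24, adjusted p = 0.00127, estimated 0.321). Late DAM, interferon and glycolysis genes did hold without the 3 low arrays (estimated 0.000695, 0.0445 and 0.0285).

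Against KO cuprizone, set A had 0 genes past the threshold with limma and 1292 at an unadjusted p under 0.05. The count was 263 without KO cuprizone 1 and 3 without KO cuprizone 3, and 190 with array weights. Cst7 stood at -1.83 ± 0.36 (log2, SE, n = 3 and 3, adjusted p = 0.122), Clec7a at -1.06 ± 0.18 (adjusted p = 0.0859), Itgax at -0.79 ± 0.23, Axl at -0.49 ± 0.22, Lpl at -0.21 ± 0.27 and Hmox1 at 0.66 ± 0.25. Neutrophil genes were lower by a mean of -1.39 with 7 of 9 lower adjusted over the list alone (adjusted p = 1.09e-09, estimated 0.0426). Late DAM genes were lower by a mean of -0.41 with 10 of 19 adjusted over the list alone (adjusted p = 3.94e-09, estimated 0.154). The immediate-early list was higher in the same arrays by a mean of 0.80 with 15 of 24 adjusted over the list alone (adjusted p = 4.93e-15, estimated 0.211). Inflammatory cytokines (mean 0.62, adjusted p = 1.04e-05), border macrophage genes (mean 0.52, adjusted p = 1.09e-05) and MHC class II genes (mean -0.29, adjusted p = 0.000487) were called, with estimated adjusted p = 0.33, 0.256 and 0.148. Without the 3 low arrays KO cuprizone 1 was alone in its group. Inflammatory cytokines and border macrophage genes then pointed the other way, and the immediate-early mean was 0.14.

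Set B differed from KO cuprizone in 19 genes, 11 higher and 8 lower, with 1114 at an unadjusted p under 0.05. The higher share was 57.9%, and it was 38.9% of 18 after quantile normalization and 75% of 32 after centring each array on its median. Cxcl10 was higher by 2.53 ± 0.44 (log2, SE, n = 3 and 3), Osm by 1.46 ± 0.29, and Ccrl2, H2-Q5, Gpr84, Irf1, Nt5dc3 and Slc25a45 by between 0.74 and 1.19. S100a8 and S100a9 were lower by -3.77 ± 0.63 and -3.59 ± 0.64 (not exact), and Dcaf17, Iqcn, Orm2 and Alyref2 by between -0.83 and -0.63. Cst7 (0.66 ± 0.36), Hmox1 (0.68 ± 0.25), Itgax (-0.17), Lpl (0.05), Axl (0.01) and Clec7a (0.00) did not pass. The count was 218 without KO cuprizone 1 and 1 and 4 without KO cuprizone 2 and 3. It was 4, 3 and 0 without set B 1, 2 and 3, so that each of the 14 named calls was lost at least once. Inflammatory cytokines had 14 of 23 higher adjusted over the list alone (mean 0.94, adjusted p = 3.02e-15) and neutrophil genes 2 of 9 lower, 6 adjusted over the list alone (mean -1.31, adjusted p = 1.3e-06), both with estimated adjusted p = 0.129. The immediate-early list was higher in the same arrays by a mean of 0.77 (12 of 24 adjusted over the list alone, adjusted p = 2.57e-14, estimated 0.32). NRF2 genes had a mean of 0.19 (adjusted p = 0.0024), interferon genes 0.27 (adjusted p = 0.00297) and glycolysis genes 0.23 (adjusted p = 0.000302), with estimated adjusted p = 0.129, 0.663 and 0.341. Without the 3 low arrays, KO cuprizone 2 and 3 among them, KO cuprizone 1 was alone in its group. The mean was then 0.13 for inflammatory cytokines and 0.10 for the immediate-early list.

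Between the sets 1 gene passed, Cst7, which was lower in set A than in set B by -2.49 ± 0.36 (log2, SE, n = 3 and 3, adjusted p = 0.0142), with 1041 at an unadjusted p under 0.05. This comparison is the cuprizone effect on a Covi-Ox diet in KO under the titles, and its negative under the other fields. Clec7a stood at -1.06 ± 0.18 (adjusted p = 0.0658), Itgax at -0.62 ± 0.23, Axl at -0.50 ± 0.22, Apoe at -0.39 ± 0.13 and Lpl at -0.26 ± 0.27. Late DAM genes had 1 of 19 lower and 9 adjusted over the list alone (mean -0.56, adjusted p = 1.13e-13, estimated 0.213). Cholesterol efflux genes (mean -0.32, adjusted p = 5.86e-05), glycolysis genes (mean -0.23, adjusted p = 5.86e-05) and inflammatory cytokines (mean -0.32, adjusted p = 0.000543) were lower in set A and border macrophage genes higher (mean 0.50, adjusted p = 2.99e-06), with estimated adjusted p = 0.213, 0.25, 0.459 and 0.25. The count was 0 without any of set A 1, 2 and 3 and set B 2 and 3, and 8 without set B 1. It was 72 without the 3 low arrays, none of which belongs to either set, so only the shared spread differs, and late DAM and cholesterol efflux genes then had estimated 0.000214 and 0.033.

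Against WT both, set A had 1136 genes past the threshold, 474 higher and 662 lower, and set B 460, 150 higher and 310 lower. After quantile normalization set A had 616 higher and 576 lower, so its majority depends on the scaling. The titles make the first the comparison of genotypes on both additives, and the other fields the second. Itgax was lower by -4.90 ± 0.23 in set A and -4.28 ± 0.23 in set B (log2, SE, n = 3 and 3), Lpl by -4.40 ± 0.27 and -4.14 ± 0.27, Cst7 by -5.23 ± 0.36 and -2.74 ± 0.36, Clec7a by -4.01 ± 0.18 and -2.95 ± 0.18, Axl by -3.42 ± 0.22 and -2.92 ± 0.22 and Apoe by -1.05 ± 0.13 and -0.65 ± 0.13. Tmem119 was higher by 0.71 ± 0.09 and 0.54 ± 0.09 and P2ry12 by 0.45 ± 0.08 and 0.36 ± 0.08. These 8 genes passed in both comparisons, P2ry12 in set B not without set B 1 or WT both 2. Cx3cr1 and Csf1r passed in set A (0.46 and 0.31) and not in set B (0.25 and 0.15), and neither passed between the sets (0.20 ± 0.09 and 0.15 ± 0.08, adjusted p = 0.512 and 0.585). Late DAM genes were lower for 19 of 19 members in set A (19 adjusted over the list alone, mean -2.56, estimated adjusted p = 0.00267) and 16 in set B (17 adjusted over the list alone, mean -2.01, estimated adjusted p = 0.00123). Cholesterol synthesis was called only in set B minus WT both among all 18 comparisons (mean -0.16, adjusted p = 0.0189, estimated 0.144). Without WT both 2 the set A count was 718, and without set A 3 it was 740.

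Against WT Covi-Ox, set A had 19 genes past the threshold (8 higher, 11 lower) and set B 29 (15 higher, 14 lower, 51.7% higher, and 27.8% of 18 after centring each array on its median). Unadjusted p-values under 0.05 numbered 580 and 1126. Trem2 was lower by -3.68 ± 0.11 and -3.54 ± 0.11 (log2, SE, n = 3 and 3), and Clec7a by -1.08 ± 0.18 in set A (adjusted p = 0.0125) and by -0.01 ± 0.18 in set B, where it did not pass. The set A call of Clec7a was lost without set A 1 or 3 or WT Covi-Ox 2 or 3. Itgax stood at -1.11 ± 0.23 (adjusted p = 0.0523) and -0.49 ± 0.23, and Cst7 at -1.19 ± 0.36 and 1.31 ± 0.36, without passing. The set A count fell to as low as 9, without WT Covi-Ox 3, and the set B count to between 14 and 10 without any 1 array. Of the lists, 5 were called for set A and 8 for set B, none with an estimated correlation (2 each without the 3 low arrays). TREM2 and DAP12 signalling was called only in set B minus WT Covi-Ox among all 18 comparisons (mean -0.18, 2 of 16 lower adjusted over the list alone, adjusted p = 0.0347, estimated 0.347).

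Markers of other cell types than monocytes, neutrophils and border macrophages were not called in any of the 18 comparisons. In WT cuprizone minus WT control the oligodendrocyte list had a mean of 0.05 (8 measured, adjusted p = 0.528), the astrocyte list -0.15 (7 measured, adjusted p = 0.391), the endothelial list 0.29 (5 measured, adjusted p = 0.203) and the oligodendrocyte precursor list 0.36 (3 measured, adjusted p = 0.14). The T and NK cell, B cell, dendritic cell and monocyte lists had adjusted p = 0.566 or higher there. Single members rose all the same, Flt1 of the endothelial list by 1.46 ± 0.29, Cspg4 of the precursor list by 1.04 ± 0.20, and Cd22 and Fn1.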

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

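The tests of the 3 weighed patterns were chosen only after the results had been seen, while the splits of the arrays and the differences between groups were planned.

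The cuprizone effect differed between WT and KO in 27 genes, by the test of the difference itself. On the log2 scale KO minus WT was -2.88 for Itgax, -2.82 for Mmp12, -2.77 for Gpnmb, -2.77 for Bhlhe40, -2.56 for Lpl, -2.19 for Axl, -2.15 for Capg and -2.10 for Fam20c. It was -1.85 for Clec7a, -1.61 for Olr1, -1.39 for Gla and -0.80 for Cxcl16. Positive differences were 1.81 for Eif2s3y, lowest in KO control (5.91 and 6.18), 1.29 for Clec12a, 1.17 for Zranb1, 0.92 for Csmd3 and 0.83 for Maml2.

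By list, the mean of that difference was -1.409 for late DAM genes, -0.696 for lipid uptake, -0.613 for cholesterol efflux, -0.465 for glycolysis, -0.426 for interferon, -0.400 for inflammatory cytokines, -0.278 for cell cycle, -0.267 for MHC class I, -0.219 for NRF2 genes and -0.208 for oxidative phosphorylation. It was 0.253 for homeostatic genes and 0.813 for neutrophil genes. Only the late DAM and lipid uptake calls held with an estimated correlation. Without the 3 arrays low in immediate-early genes KO cuprizone 1 was alone in its group. That fit takes its spread from other groups, so it does not decide these calls.

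The cuprizone effect in WT differed between the diets with and without Covi-Ox in 3 genes, Olr1 (1.97), Ccn1 (-1.86) and Tagap (-1.43). By list the mean difference was 1.443 for neutrophil genes, 0.811 for monocyte genes, 0.795 for inflammatory cytokines and -0.214 for homeostatic genes, none of which held with an estimated correlation. Without those arrays the monocyte and homeostatic calls did (adjusted p = 0.0224 each), and the inflammatory mean was 0.423.

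The 6 arrays of each comparison of 3 and 3 were also split in all 10 ways, which are too few for a share under 0.05. The real split of KO and WT cuprizone gave 450 genes, the most of the 10, and the highest other gave 356. That other split sets WT cuprizone 3, KO cuprizone 2 and KO cuprizone 3 against the rest, the 3 arrays low in immediate-early genes, so it follows a structure of the samples that is not the genotype. Without those arrays the comparison gave fewer than 450 genes, but KO cuprizone 1 is then the only KO array left. With the immediate-early mean as a covariate 807 genes passed. WT both against WT cuprizone gave 18 genes and at most 1 in another split, and WT both against WT Covi-Ox gave 925 and at most 1. Set A against KO cuprizone gave 0, as did all 10 splits, and set B against KO cuprizone 19 with at most 3. Set A against set B gave 1 and no other split any. Against WT both, set A gave 1136 with 0 in any other split and set B 460 with at most 1. Against WT Covi-Ox the sets gave 19 and 29, with 0 in any other split.

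Sets A and B differed in the 154 genes that cuprizone raised at least 2-fold in WT on Covi-Ox, chosen on WT arrays only. Their mean was 6.32 ± 0.05 in set A and 6.64 ± 0.07 in set B (log2, SD, n = 3 each), a difference of -0.32 with no overlap, 121 genes lower in set A, and an exact permutation p = 0.1, the smallest for 3 against 3. KO control had 6.17 and KO cuprizone 6.44. By the titles set A would be on cuprizone and lie above, so exchanged titles may account for the order, as a hypothesis. Different activation of the sets during dissociation predicted immediate-early means without overlap, but these overlapped and differed by 0.036. Other differences in isolation cannot be told apart from exchanged titles. A KO response opposite to WT is argued against on chow, where the mean ran from 6.34 to 6.52 on the KO cuprizone arrays. It was 6.21 and 6.12 on the KO control arrays. Of the 154 genes 116 had a KO effect above 0 (median 0.24), but 0 were called higher, and genes are not independent. An opposite response on Covi-Ox was not tested.

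Neutrophil genes were lower on the diets with Covi-Ox, with overlapping list means of 5.14 to 6.41 on the 12 arrays with it and 6.22 to 7.69 on the 10 without. Normalization acting on level is argued against, since in WT Covi-Ox minus control 7 of the 9 members fell further than all 200 other genes nearest to them in WT control level, whose medians lay between -0.06 and 0.03. Fewer neutrophils among the sorted cells may account for it, but the falls restate the pattern and do not test this. The median was -2.22, with S100a8 at -5.99 (10.39 to 4.40, below the array medians), S100a9 from 10.52 to 5.28, Camp at -2.22, Ngp at -2.57, Lcn2 at -2.38, Retnlg at -1.99, Hp at -0.78, Mmp9 at -0.15 and Csf3r, also in microglia, at 0.22. A sort for F4/80 should remove neutrophils, and no member is in another list. A separate isolation day cannot be told apart from the diet, since the labels give no day and 1 array without Covi-Ox lay within the range of those with it, and an effect of tocopherols on the cells was not tested.

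In 18 genes, Trem2 included, all 11 KO arrays lay on one side of all 11 WT arrays, where chance gives 0.000284% per gene. A segment around Trem2 from another strain cannot contain the 14 genes on other chromosomes, and an effect of such a segment on them was not tested. Their KO minus WT ran from -5.46 for G530011O06Rik, -2.78 for Mid1 and -2.37 for Lrmda to 2.79 for Rasgrf2 and 0.85 for both Csmd3 and Nnt. On the chromosome of Trem2 lay Enpp5 (-0.99), Glo1 (0.95) and Tnfrsf21 (0.40), with 59, 230 and 61 tested genes between, against 0.873 expected (one-sided Fisher exact p = 0.0535), so such a segment cannot be told apart from chance for these 3. Other strain differences between the colonies could account for the rest, since Nnt is known to be deleted in a common substrain, but the labels give no substrain and its 0.85 cannot decide. A dependence of these genes on Trem2 stays open, as untested.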

How the results depend on the processing

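The alternatives without the 3 low arrays and with the immediate-early covariate were chosen after the results had been seen, and the second is circular for its own list. Of the count values and correlations under alternatives 206 stayed within 1.5 times (or the replicate spread) and 176 moved. Of the single-gene values 7995 kept their side of the threshold, 1332 were no longer past it, 89 newly passed and none passed the other way. Of the list calls 586 held, 257 were lost and 17 turned. The Trem2 difference on control of -3.89 kept its call under every alternative run. The cause of a change was not tested unless stated. A slash stands for against. The genotype difference and the diet difference are the differences of cuprizone effects between KO and WT and between WT diets with and without Covi-Ox.

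A change of at least 2-fold and an adjusted p under 0.01 select from the called genes by construction. At 2-fold the count was 101 for WT cuprizone/control, 94 for KO/WT on cuprizone, 6 for WT both/cuprizone, 168 for WT both/Covi-Ox, 26 for set B/KO control and 5 for set B/KO cuprizone. It came to 196 for set A/WT both, 136 for set B/WT both, 10 for set A/WT Covi-Ox and 16 for set B/WT Covi-Ox. At 0.01 it was 104 for WT cuprizone/control, 0 for KO cuprizone/control, 7 for the genotype difference, 5 for KO/WT on control, 147 for KO/WT on cuprizone and 5 for WT both/cuprizone. It came to 444 for WT both/Covi-Ox, 1 for set A/KO control, 4 for set B/KO control, 0 for set B/KO cuprizone, 0 for set A/set B and 576 for set A/WT both. There were 260 for set B/WT both, 8 for set A/WT Covi-Ox and 12 for set B/WT Covi-Ox.

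With only the arrays compared, which leaves fewer arrays for the spread, the count was 9 for WT cuprizone/control, 0 for KO cuprizone/control, 4 for the genotype difference, 5 for KO/WT on control, 39 for KO/WT on cuprizone and 18 for WT Covi-Ox/control. It came to 2 for WT both/cuprizone, 3 for set B/KO control, 1 for set A/KO cuprizone, 0 for set B/KO cuprizone, 27 for set A/set B and 64 for set B/WT Covi-Ox. With array weights the count was 0 for KO cuprizone/control, 12 for the genotype difference, 5 for KO/WT on control, 52 for WT Covi-Ox/control, 150 for WT both/cuprizone and 1751 for WT both/Covi-Ox. It came to 27 for the diet difference, 0 for set A/KO control, 2 for set B/KO control, 190 for set A/KO cuprizone, 169 for set B/KO cuprizone and 91 for set A/set B. There were 1879 for set A/WT both, 885 for set B/WT both, 36 for set A/WT Covi-Ox and 174 for set B/WT Covi-Ox.

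With no filter the count was 0 for KO cuprizone/control, 9 for WT both/cuprizone, 12 for set B/KO cuprizone and 15 for set B/WT Covi-Ox. With the stricter filter it was 14 for KO cuprizone/control, 10 for WT both/cuprizone, 5 for set A/KO cuprizone, 30 for set B/KO cuprizone and 13 for set A/set B. After quantile normalization the count was 12 for KO cuprizone/control, 2 for set A/KO cuprizone and 2 for set A/set B. With each array centred on its median it was 711 for KO/WT on cuprizone, 32 for set B/KO cuprizone and 18 for set B/WT Covi-Ox. With the trend and robust options the count was 11 for set B/KO cuprizone and 10 for set A/set B. The mean of all probe sets of a gene kept every count within 1.5 times.

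With the replicate number as a block the count was 183 for WT cuprizone/control, 0 for KO cuprizone/control, 1 for set A/KO control, 24 for set B/KO control, 1 for set A/KO cuprizone, 3 for set A/set B and 19 for set B/WT Covi-Ox. No list count changed by more than 1.5 times with the block. The numbers do not pair the arrays: residuals of arrays with the same number had a mean r of -0.008 (range -0.227 to 0.254) and those with other numbers 0.004, 3 of 71 pairs lay above 0.1, and 3 of 22 arrays matched their own number best.

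After leaving out the 3 arrays the count was 184 for WT cuprizone/control, 9 for KO cuprizone/control, 83 for KO/WT on cuprizone, 36 for WT Covi-Ox/control, 150 for WT both/cuprizone and 40 for the diet difference. It came to 33 for set A/KO control, 263 for set B/KO control, 5 for set A/KO cuprizone, 10 for set B/KO cuprizone, 72 for set A/set B, 32 for set A/WT Covi-Ox and 111 for set B/WT Covi-Ox. With the covariate it was 188 for WT cuprizone/control, 2 for KO cuprizone/control, 88 for the genotype difference, 807 for KO/WT on cuprizone, 27 for WT Covi-Ox/control and 73 for WT both/cuprizone. It came to 7 for the diet difference, 13 for set A/KO control, 249 for set B/KO control, 3 for set A/KO cuprizone, 60 for set A/set B and 66 for set B/WT Covi-Ox.

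Across genes the cuprizone effects of the genotypes had r = 0.311, and 0.266 with the block, 0.253 with no filter, 0.39 with the stricter filter, 0.124 without the 3 arrays and 0.089 with the covariate. With 1 array left out it ran from 0.208 to 0.339.

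With an estimated correlation the number of called lists was 6 for WT cuprizone/control, 0 for KO cuprizone/control, 2 for the genotype difference, 0 for KO/WT on control, 4 for KO/WT on cuprizone and 1 for WT Covi-Ox/control. It came to 0 for WT both/cuprizone, 10 for WT both/Covi-Ox, 0 for the diet difference, 0 for set A/KO control, 0 for set B/KO control and 1 for set A/KO cuprizone. There were 0 for set B/KO cuprizone, 0 for set A/set B, 8 for set A/WT both, 3 for set B/WT both, 0 for set A/WT Covi-Ox and 0 for set B/WT Covi-Ox. With fry it was 3 for KO cuprizone/control, 2 for the genotype difference, 0 for KO/WT on control, 2 for WT both/cuprizone, 0 for the diet difference and 5 for set B/KO control. It came to 4 for set A/KO cuprizone, 3 for set B/KO cuprizone, 3 for set A/set B, 0 for set A/WT Covi-Ox and 0 for set B/WT Covi-Ox. Leaving out the 3 arrays, the number was 5 for KO/WT on control, 15 for WT both/cuprizone, 11 for the diet difference and 4 for set A/KO control. With the covariate it was 4 for KO cuprizone/control, 5 for KO/WT on control, 11 for WT both/cuprizone and 8 for the diet difference.

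These lists turned direction without the 3 arrays, with the adjusted p there: inflammatory cytokines and border macrophage genes in KO cuprizone/control (1.28e-07 and 0.00767), inflammatory cytokines and cell cycle genes in the genotype difference (0.638 and 0.955), cell cycle and ATF4 genes in KO/WT on cuprizone (0.417 and 0.753), immediate-early genes in WT both/cuprizone (0.0121), inflammatory cytokines and border macrophage genes in set A/KO cuprizone (0.000328 and 0.148) and homeostatic genes in set B/KO cuprizone (0.4). All but WT both/cuprizone rest on 1 KO cuprizone array, so these turns are not settled. With the covariate cholesterol efflux, glycolysis and immediate-early genes (0.952 each) and inflammatory cytokines (0.00118) turned in KO cuprizone/control, inflammatory cytokines and immediate-early genes in set A/KO cuprizone (0.00426 and 0.512) and immediate-early genes in set B/KO cuprizone (0.544).

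With 1 array of the compared groups left out in turn, the count ran from 69 to 428 for WT cuprizone/control, 0 to 765 for KO cuprizone/control, 6 to 265 for the genotype difference, 5 to 701 for KO/WT on control, 207 to 529 for KO/WT on cuprizone and 2 to 4 for WT Covi-Ox/control. It ran from 4 to 104 for WT both/cuprizone, 531 to 659 for WT both/Covi-Ox, 1 to 32 for the diet difference, 0 to 925 for set A/KO control, 0 to 876 for set B/KO control and 0 to 263 for set A/KO cuprizone. It ran from 0 to 218 for set B/KO cuprizone, 0 to 8 for set A/set B, 718 to 809 for set A/WT both, 311 to 324 for set B/WT both, 9 to 18 for set A/WT Covi-Ox and 10 to 14 for set B/WT Covi-Ox. Where a group kept 1 array, it was assumed to vary like other groups.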

Other observations

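Of the tests in this part only the fit without the 3 arrays low in immediate-early genes, none of which is compared here, was chosen after the results had been seen.

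Interferon genes were higher in both unresolved KO sets than in WT on Covi-Ox. In set A 1 of 24 measured members passed and 6 were higher adjusted over the list alone (mean 0.43, adjusted p = 2.29e-16, estimated 0.165 with a correlation taken from the data). In set B it was also 1 of 24, with 14 higher adjusted over the list alone (mean 0.52, adjusted p = 5.66e-14, estimated 0.271). Without the 3 arrays the estimated adjusted p was 0.0275 and 0.0428. Cell cycle genes were higher too, by means of 0.19 and 0.28 (adjusted p = 0.00198 and 1.77e-05, estimated 0.411 and 0.332, the second 0.0391 without the 3 arrays), though no member passed. Late DAM genes were lower in set A, with 2 of 19 called and 5 adjusted over the list alone (mean -0.45, adjusted p = 1.9e-12, estimated 0.226, and 0.000292 without the 3 arrays). Neutrophil genes moved with set B in this comparison, by a mean of 0.52 (adjusted p = 0.0424, estimated 0.43).

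Against WT both, homeostatic microglia genes were higher in set A for 16 of 20 members and 17 adjusted over the list alone (mean 0.52, adjusted p = 9.28e-18, estimated 0.0291). In set B 11 were higher and 16 adjusted over the list alone (mean 0.44, adjusted p = 1.52e-17, estimated 0.0562, and 0.00103 without the 3 arrays). The neutrophil and immediate-early lists were not called in either of these comparisons.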
